A study of Arabidopsis thaliana with 6 samples.

How the data were processed

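RNA-binding sites of ECT2 were profiled by FA-CLIP in 14-day-old seedlings, with 2 libraries each for FA-CLIP, mock and input. Precipitated RNA (FA-CLIP and mock) was made into libraries with a small RNA kit and input RNA with an RNA library kit, so input and precipitates differ by kit as well as by precipitation. The submitters' processing notes name cutadapt and Bowtie, without versions, and the TAIR10 build. The program that called the sites, the counter and the gene annotation are not given in the sources used here.

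The deposited mock and FA-CLIP files list sites by transcript, and the values used from them are counts of conversion events per site, per the file headers. They are whole numbers of 2 or more, not scaled to library size. The deposited input files hold 1 value per gene, in FPKM. That unit was inferred from the layout of the headers and from the values. Whether the input libraries were scaled to each other is not stated, and the number of reads behind them is unknown. Site lists and FPKM are different units, and the site lists hold no value for genes without a site. For site lists the design fixed in advance set no test of values across libraries, so FA-CLIP and mock events, which share a unit, were compared as sets and no gene-level test was made. With 2 libraries per group, an exact permutation test cannot go below p = 0.333.

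A site listed for several transcripts was counted once. Sites were compared on the same strand with bedtools 2.31.1, with a minimum overlap of 1 nt. A reproducible site joins overlapping sites of both FA-CLIP replicates. Chance overlap came from 100 placements of the replicate 2 sites within their genes. Each site was assigned by its midpoint to a region of 1 representative transcript per gene, the one with the longest CDS. Shares of sites or genes carry 95% Wilson intervals, which cover counting error only. Means are given with the SD of 2 libraries.

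For motifs, each site was compared with a window of the same length from the same region of the same gene outside the sites, 1 window per site, and 7 preset motifs were counted as present or absent. Fisher's exact test was two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Other controls were dinucleotide-shuffled sites, windows with the same number of T, and both sequences extended by 25 nt.

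For 14 gene lists, members with input above 0 and a reproducible site were compared with the 20 nuclear protein-coding genes of nearest input per member, by Fisher's exact test (two-sided). A gene near several members was counted once, so the comparison genes are not weighted by input as the members are. A recovery score, log2 of mean FA-CLIP events plus 1 over mean input FPKM times transcript length in kb, was computed for genes of 1 FPKM or more. Its list medians were compared with 10000 random lists, each member replaced by 1 of the 50 genes of nearest input. Genes are named by rule: the 15 nuclear protein-coding genes with the most events in reproducible sites (mean of 2 libraries), the 10 with the highest ratio of those events to input among genes above the median input, and the members of the YTH-domain and trichome lists. Genes of other lists are named where a list holds few members with a site.

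The comparisons, the motifs, the gene lists and the rule for named genes were fixed before the data were examined. The alternatives tried were a stricter overlap, sites with more than the median number of events, other transcript models, other motif controls, other comparison genes, and leaving out each library in turn. The recovery score, windows with the same number of T, placement within a region, thinning, the authors' location label, and motifs among mock 3' UTR and CDS sites, and shares without 2 genes were added after seeing the data. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data: 2410 of 2410 planted shared sites were found, 0 of 7 motifs passed in 4000 pairs without a planted motif, and 5 of 100 random gene lists had p under 0.05. A planted log2 shift of 1.0 was returned as 1.23. The planted shared sites were copies shifted by less than their width, so they had to overlap. The simulated motif sites were placed at random and were not selected for conversion events. The random lists were not concentrated at high input. These simulations thus check the calculations and not biases of the called sites or of the comparison genes.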

Results

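RNA recovered with ECT2 was profiled in Arabidopsis seedlings. ECT2 is a YTH-domain protein that binds RNA carrying N6-methyladenosine (m6A). In formaldehyde crosslinking and immunoprecipitation (FA-CLIP), crosslinked RNA is digested with RNase T1 and precipitated with the protein. All 6 libraries came from 14-day-old seedlings, in 3 groups of 2. The input group held RNA of plants that carry FLAG-tagged ECT2 in the ect2 mutant, without precipitation. The FA-CLIP group held RNA precipitated with anti-FLAG beads from the same kind of plants. The mock group held RNA precipitated with the same beads from wild-type Col-0 plants. The FA-CLIP libraries listed 41707 sites with 901178 conversion events in replicate 1 and 41471 sites with 830355 events in replicate 2. The mock libraries listed 3440 sites with 489805 events and 3848 sites with 653262 events. The input tables gave FPKM above 0 for 25823 genes in replicate 1 and 25981 in replicate 2, and their read depth is unknown. A single gene, AT2G01021, took 33.4% of the summed FPKM in input replicate 1 and 57.5% in input replicate 2. Across the 26690 nuclear protein-coding genes the input replicates had a Spearman correlation of 0.988, a correlation across genes, which are not independent replicates. Intervals of shares are 95% Wilson intervals and cover counting error only.

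The precipitation from tagged plants was set against the mock to ask which RNA the beads hold without the tag. Nuclear protein-coding genes took 60.3% ± 8.05 (SD, n = 2) of the events in FA-CLIP and 5.895% ± 0.471 (SD, n = 2) in the mock. AT2G01021 and AT5G45720 made up 36.1% and 44.8% of these events in the mock libraries and 2.77% and 0.727% in FA-CLIP, and the only reproducible site of AT5G45720 lay in no annotated mRNA region. Without the 2 genes, a setting added after the data had been seen, the shares were 59.3% ± 8.78 and 3.52% ± 0.641. Ribosomal RNA took 17.3% ± 2.64 of FA-CLIP events and 37.5% ± 3.41 of mock events. Transfer RNA took 6.21% ± 3.29 in FA-CLIP and 12.6% ± 1.87 in the mock. Chloroplast genome RNA took 7.19% ± 0.313 in FA-CLIP and 17.01% ± 0.486 in the mock. Each of these differences was larger than the spread between replicates. Shares add up to the same total in every library, so a higher mRNA share lowers the others by construction. The ratios of FA-CLIP over mock were 0.46 for ribosomal, 0.49 for transfer and 0.42 for chloroplast RNA. These lower shares are therefore not results separate from the mRNA share. MicroRNA loci took 17.1% ± 0.634 of mock events, and in FA-CLIP 10.5% in replicate 1 and 1.95% in replicate 2. Both FA-CLIP values lay below the mock mean, and the FA-CLIP replicates differed widely from each other. With 2 libraries per group an exact permutation test cannot go below p = 0.333, and no test across libraries was run.

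Protein-coding genes listed by FA-CLIP were mostly absent from the mock. A reproducible site, meaning overlapping sites in both FA-CLIP libraries, was found in 8399 nuclear protein-coding genes. Of these, 7496 had no site in either mock library and 903 did. The mock libraries listed 717 and 832 such genes, 1098 in either and 451 in both. The FA-CLIP libraries held 39265 and 39004 sites in protein-coding genes against 1513 and 1854 in the mock, a ratio of means of 23.2. After the expected thinning of every library to 489805 events the ratio was 18.6. The lists give only sites of 2 or more events, so a gene missing from a list is not shown to be unbound.

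Replicate FA-CLIP libraries recovered many of the same places in the same mRNAs. In replicate 1, 65.2% (64.7 to 65.6) of the sites overlapped a site of replicate 2 by at least 1 nt, and 66.95% (66.5 to 67.4) of replicate 2 sites overlapped one of replicate 1. Across the 9270 nuclear protein-coding genes listed in both, events per gene had a Spearman correlation of 0.873, across genes. When replicate 2 sites were moved at random within their genes, 16.1% ± 0.166 (SD, 100 placements) overlapped a replicate 1 site, against 66.8% as listed, a ratio of 4.14. When they were moved only within the same 5' UTR, CDS, 3' UTR or intron, 45.5% ± 0.199 overlapped, against 66.6% as listed, a ratio of 1.46. The listed overlap exceeded all 100 placements of either kind (permutation p = 0.0099, the smallest they can give, one-sided). Joining the overlapping sites gave 22051 reproducible sites, with a median width of 47 nt and a median of 2 per protein-coding gene that held any. When at least 50% of each site had to overlap, the share of replicate 1 sites fell to 36.7%. In the mock, 67.5% of replicate 1 sites overlapped a site of replicate 2 by at least 1 nt, and 61.0% the reverse. With 50% of each site the mock shares were 48.05% and 42.96%. Overlap between replicates was thus of similar size or larger without the tagged protein. These shares cover all classes of RNA, which the mock and FA-CLIP lists hold in different proportions.

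Sites in mRNA and sites in other RNA differed in their overlap with the mock. Of 20519 reproducible sites in nuclear protein-coding genes, 7.84% (7.48 to 8.22) overlapped a mock site. Of the 1532 reproducible sites in ribosomal, transfer, small nuclear, small nucleolar, microRNA, organelle and other genes, 85.6% (83.7 to 87.2) did. Over all 22051 reproducible sites the share was 13.2% (12.8 to 13.7), and 27.65% (27.1 to 28.2) lay in a gene that a mock library listed. The overlap was 7.705% when 50% of each site had to overlap. In protein-coding genes the mock listed only 1513 and 1854 sites, which limits the share of FA-CLIP sites that can overlap them. In the other direction, over all classes, 80.8% and 75.1% of mock replicate 1 sites overlapped a site of FA-CLIP replicates 1 and 2. For mock replicate 2 the shares were 79.6% and 73.5%. Most places listed in the mock were thus also listed in FA-CLIP. The lists were called separately in each library, so these shares compare sets and carry no test across libraries.

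FA-CLIP sites lay mainly in 3' UTRs, and mock sites mainly in coding sequence. The 3' UTR held 63.6% ± 8.07 (SD, n = 2) of the FA-CLIP sites assigned to a protein-coding gene and 26.8% ± 0.904 (SD, n = 2) of the mock sites. Coding sequence held 29.05% ± 6.88 of FA-CLIP sites and 51.02% ± 0.883 of mock sites, and introns held 1.74% ± 0.0883 and 11.6% ± 1.75. Reproducible sites were in the 3' UTR in 71.6% (71.0 to 72.2) of cases, at 5.60 sites per kb of 3' UTR against 0.423 per kb of CDS and 0.346 per kb of 5' UTR, in the 8366 genes that held them. In the mock the density was 1.79 and 1.89 per kb of 3' UTR and 0.969 and 1.099 per kb of CDS. The FA-CLIP replicates differed from each other, with 57.9% (57.4 to 58.4) of replicate 1 sites and 69.3% (68.9 to 69.8) of replicate 2 sites in the 3' UTR, a difference beyond counting error. Both were above both mock libraries, which had 26.2% and 27.5%.

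**Figure D1:**
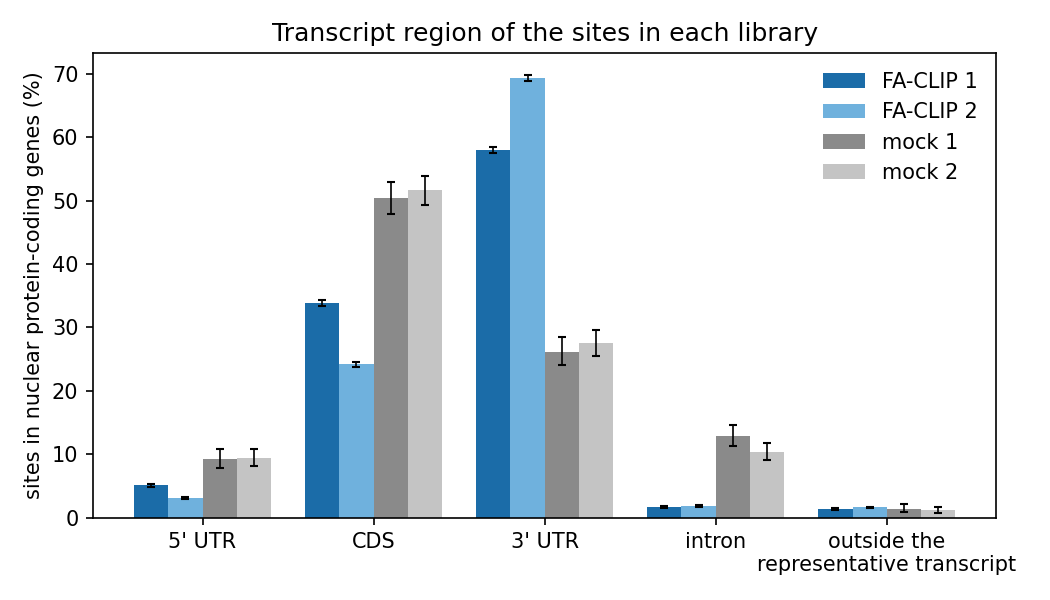
Share of the sites assigned to nuclear protein-coding genes (y axis, %) by transcript region (x axis) in the 2 FA-CLIP and the 2 mock libraries, with 95% Wilson intervals as error bars. The 3' UTR bars reach 57.9% and 69.3% in FA-CLIP and 26.2% and 27.5% in the mock.

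Within 3' UTRs, the 14655 reproducible sites had a median distance of 116 nt from the stop codon. Their midpoints lay at a median of 40.03% of the 3' UTR's length from its start, against 49.7% for sites placed at random in the same 3' UTRs. In the mock the 3' UTR sites lay at medians of 30.1% and 30.2%. The mock values rest on 396 and 509 sites.

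**Figure D2:**
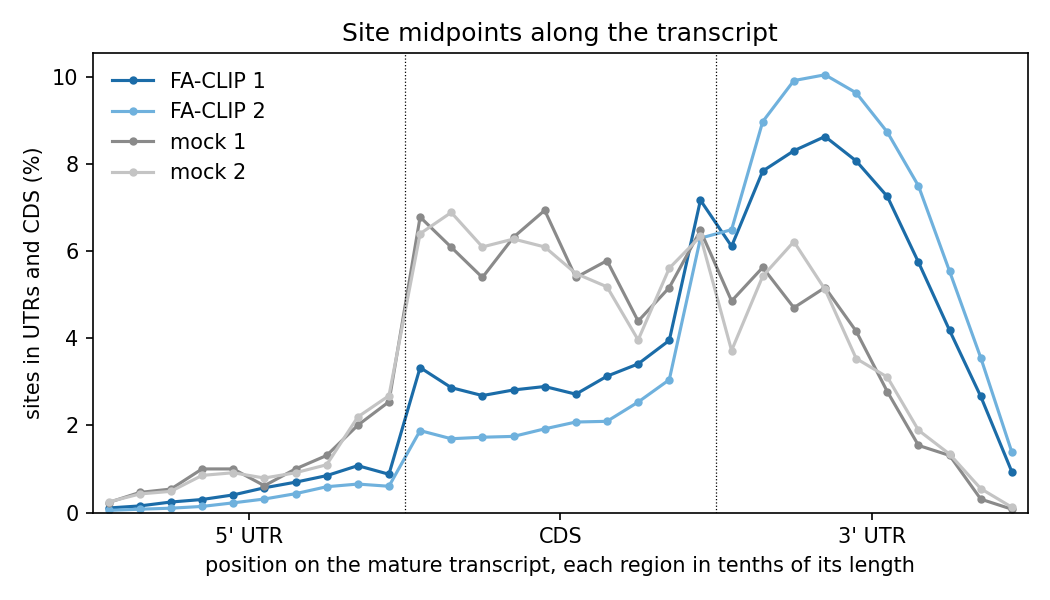
Site midpoints along the mature transcript, with the 5' UTR, CDS and 3' UTR each divided into 10 bins of equal length (x axis) and the share of sites in each (y axis, %) for the 4 precipitated libraries. The FA-CLIP lines rise at the end of the CDS and are highest within the 3' UTR, while the mock lines are high along the CDS.

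The motif comparison asked which short sequences FA-CLIP sites hold, by Fisher's exact test on 15263 pairs of a reproducible site and a window. UGUAY was in 16.8% of the reproducible sites and 10.3% of control windows from the same region of the same gene, a log2 odds ratio of 0.82 (exact test, adjusted p = 2.1e-62), and in the mock it had 0.08 and 0.24 (exact test, adjusted p = 0.848 and 0.421). URUAY, of which UGUAY is a part, was in 26.0% and 19.8% (log2 odds ratio 0.51, exact test, adjusted p = 5.3e-38), and UGUAA in 11.4% and 6.97% (0.785, adjusted p = 2.0e-41). UGUAA had mock log2 odds ratios of 0.87 and 0.835, which did not pass (exact test, adjusted p = 0.0595 and 0.0596). Under other controls UGUAA passed in the mock, at 1.48 in replicate 1 against windows with the same number of U (exact test, adjusted p = 0.00187), at 0.89 in replicate 1 against shuffled sites (adjusted p = 0.0121) and at 0.80 in replicate 2 after extension (adjusted p = 3.4e-05). The other mock library did not pass in any of these, at 0.51, 0.45 and 0.38. Under each of these controls UGUAA thus passed in a single mock library, though the values of the other were also above 0. The mock comparisons rest on far fewer pairs, 1292 and 1585 against windows from the same region. A mock value that did not pass therefore does not show that the excess was absent. The m6A consensus DRACH was in 55.7% and 52.7% (0.18, exact test, adjusted p = 1.2e-07) and RRACH in 43.3% and 41.3% (0.12, adjusted p = 4.8e-04). The mock had similar or higher values for DRACH, 0.17 and 0.26 (exact test, adjusted p = 0.315 and 0.0633), and for RRACH, 0.15 and 0.27 (exact test, adjusted p = 0.325 and 0.0633), which did not pass over all regions. By region, reproducible 3' UTR sites had 0.10 for DRACH (exact test, adjusted p = 0.0166) and 0.06 for RRACH, which did not pass (adjusted p = 0.131), and CDS sites had 0.46 and 0.31 (exact test, adjusted p = 4.1e-11 and 6.1e-06). Mock CDS sites had 0.52 and 0.46 for DRACH, which passed in both libraries (exact test, adjusted p = 0.00808 and 0.0179), and 0.65 and 0.32 for RRACH, which passed in replicate 1 (exact test, adjusted p = 0.00502 and 0.128). Mock 3' UTR sites passed for neither, at -0.45 and -0.15 for DRACH and -0.53 and 0.22 for RRACH. The mock values by region were added after the data had been seen. GGAU was in 14.2% and 13.5% and did not pass (0.09, exact test, adjusted p = 0.061), though it passed under 5 of the alternatives. UUUUU was in 19.96% and 13.5% (0.67, exact test, adjusted p = 8.1e-51), and its direction reversed to -0.25 against windows with the same number of U and to -0.28 against shuffled sites. In 3' UTR sites URUAY had a log2 odds ratio of 0.58, in CDS sites 0.52, and in 5' UTR sites -1.32 (exact test, adjusted p = 2.4e-05). For URUAY, UGUAY, UGUAA, DRACH, RRACH and UUUUU the log2 odds ratio was above 0 in 2 of 2 FA-CLIP libraries.

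Against windows with the same number of U, the log2 odds ratio was 0.735 for DRACH, 0.75 for RRACH, 0.84 for UGUAA, 0.505 for UGUAY and 0.18 for URUAY. Against shuffled sites it was 0.07 for DRACH (exact test, adjusted p = 0.0145) and 0.36 for RRACH (adjusted p = 3.2e-35), and in the mock 0.19 and 0.04 for DRACH and 0.365 and 0.27 for RRACH, of which only RRACH in replicate 1 passed (exact test, adjusted p = 0.0121). The values with the same number of U rest on the 9925 of 20164 sites for which such a window existed, and the main comparison rests on 15263. In the mock, the 95% interval of the URUAY log2 odds ratio ran from -0.67 to 0.14 and from -0.39 to 0.32 against windows from the same region. Among 3' UTR sites alone, a comparison added after the data had been seen, URUAY had -0.11 and 0.45 in the mock (exact test, adjusted p = 0.819 and 0.216) and 0.53 and 0.57 in the FA-CLIP libraries. There UGUAY had 0.83 and 1.15 in the mock (exact test, adjusted p = 0.184 and 0.00916) and 0.80 and 0.96 in FA-CLIP, and UGUAA had 0.58 and 1.60 (exact test, adjusted p = 0.368 and 0.00126) and 0.77 and 0.85. Both passed in mock replicate 2 and neither passed in mock replicate 1. The values of mock replicate 1, 0.83 and 0.58, were also above 0, and 0.83 lay within the range of the FA-CLIP libraries. Few mock sites lay in 3' UTRs, so an excess in mock replicate 1 is not excluded. Against windows with the same number of U, mock sites had log2 odds ratios of 0.48 and 0.72 for DRACH and 0.65 and 0.74 for RRACH, so the excess of these motifs over such windows was present without the tagged protein. Sites are not replicates of each other, and Fisher's exact test (two-sided, adjusted over 7 motifs) treats them as independent.

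**Figure D3:**
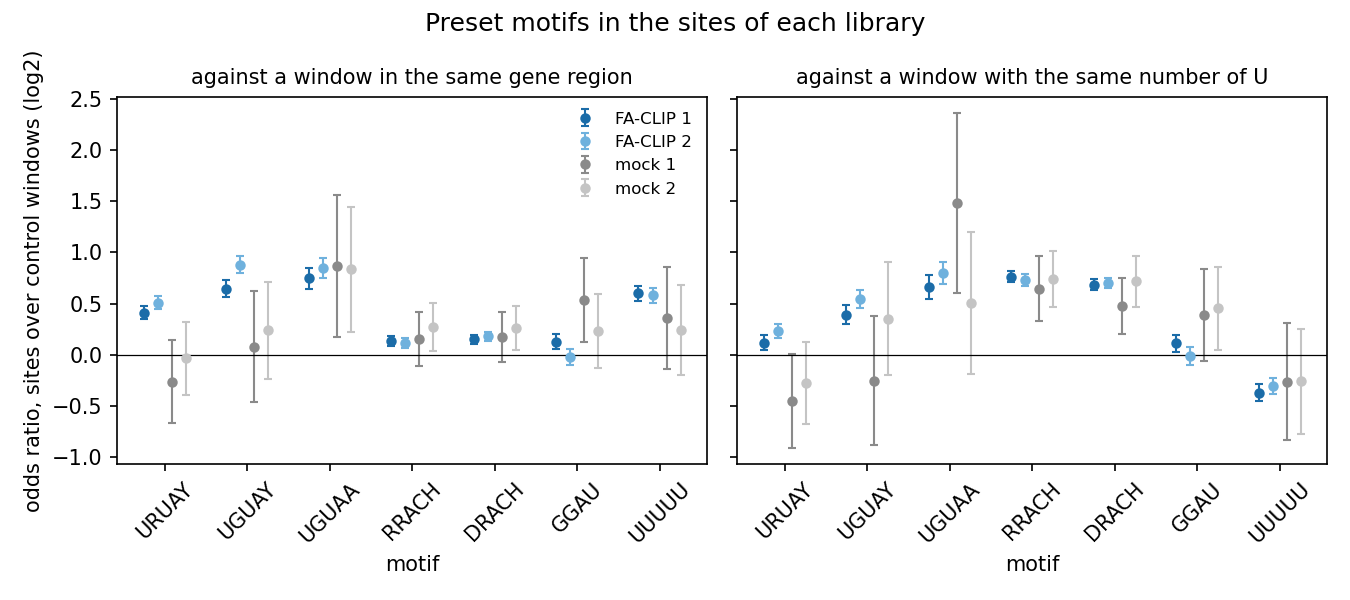
Log2 odds ratio (y axis) of 7 preset motifs (x axis) in sites over control windows for the 2 FA-CLIP and the 2 mock libraries, against windows of the same gene region (left) and windows that also hold the same number of U (right), with 95% intervals. URUAY lies above 0 in both FA-CLIP libraries in both panels and below 0 in both mock libraries, whose intervals include 0 in the left panel. UUUUU lies below 0 in the right panel in all 4 libraries.

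FA-CLIP recovery was set against the input to ask how far it follows abundance. Of the 13345 nuclear protein-coding genes above the median input of 2.65 FPKM, 59.7% (58.9 to 60.6) had a reproducible site, and of those at or below it 3.20% (2.91 to 3.51) did. When genes were ranked by input and divided into 10 bins of near-equal size, the share was 0.63% in the lowest bin and 87.1% in the highest. Mean events per gene and mean input had a Spearman correlation of 0.666 and a Pearson correlation on the log2 scale of 0.677 across 12490 genes, which are not independent replicates. The mock, set against the input in the same way, listed 7.06% (6.64 to 7.51) of the genes above the median and 1.17% (1.00 to 1.37) of the others. Its correlation with input over the 1067 genes it listed was 0.175 (Spearman, across genes). Over all 13345 genes above the median input, the mock had a Spearman correlation of 0.321 and a Pearson correlation on the log2 scale of 0.447, against 0.618 and 0.649 for FA-CLIP. FPKM and events are different units and the input was made with a different library kit, so no test of a change between input and precipitate was made for single genes.

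Among the 15 protein-coding genes with the most events in reproducible sites, 5 encode photosystem or Rubisco subunits. TCTP (AT3G16640, chromosome 3, 5669317 to 5670842), translationally controlled tumor protein, had the most, with 6893 ± 407 (SD, n = 2) events at an input of 1199 ± 141 FPKM. ARFA1E (AT3G62290), a small GTPase of vesicle traffic, had 5499 ± 2298 events, and GGT1 (AT1G23310), a photorespiratory aminotransferase, had 4601 ± 1220. PSBR of photosystem II had 3225.5 ± 1213 events and PSAL of photosystem I had 2836.5 ± 176, and PSAH-1, PSBW and the Rubisco subunit RBCS1A had 1698 ± 76.4, 1626 ± 139 and 1959 ± 308. When 50% of each site had to overlap, a setting added for single genes after the data had been seen, PSBW fell to 298.5, RBCS1A to 921, PSAH-1 to 1254, PSAL to 1781.5 and GAPA to 1521. The others were EF1A-A4, GAPA, UBC10, GRF6 and SSR16, with 1597 to 2879.5 events, and AT2G01021 and AT5G45720. AT2G01021 had 7216 and 2292 FA-CLIP events and 4741 and 10039 mock events, and AT5G45720 had 6435 and 1690 FA-CLIP events and 6283 and 6237 mock events. All 15 genes had at least 1 mock site, and the other 13 had from 0 to 183 mock events per library.

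The 10 genes with the highest ratio of events to input, among genes above the median input, included VMA10 (AT3G01390, chromosome 3, 149940 to 151572), a vacuolar ATPase subunit, with 1061.5 ± 2.12 events at 60.04 ± 4.52 FPKM. RPK2 (AT3G02130), a receptor kinase, had 358.5 ± 308 events at 3.25 ± 0.155 FPKM, 576 events in replicate 1 and 141 in replicate 2. PVA12 (AT2G45140) had 298 ± 12.7 events and MAPR2 (AT2G24940) had 118.5 ± 4.95, at an input of 0.0185 FPKM in replicate 1 and 7.58 in replicate 2. AT2G04700, a ferredoxin thioredoxin reductase subunit gene, had 1299 ± 607. With 50% overlap AT2G04700 had 242.5 and MAPR2 had 67. AT3G20362, AT2G31141, AT1G11020, AT1G77030 and AT1G31835 made up the rest. These 5 had between 151 and 801 mock events per library, and RPK2, MAPR2 and PVA12 had none. Dividing by transcript length as well kept 7 of the 10.

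Genes of trichome development were examined because ECT2 has a published role in leaf hairs (trichomes). TTG1 (AT5G24520, chromosome 5, 8370317 to 8372847), a WD40-repeat regulator, had 53.0 ± 4.24 (SD, n = 2) events in 3 reproducible sites at 12.1 ± 1.26 FPKM, and 2 of the 3 lay in the 3' UTR. DIS2 (AT1G30825, chromosome 1, 10960908 to 10963231), a subunit of the actin-nucleating ARP2/3 complex, had 18.5 ± 2.12 events in 2 sites, and ITB1 (AT2G38440, chromosome 2, 16095235 to 16101221), a SCAR protein that activates that complex, had 11.5 ± 3.54 in 2 sites, all in the 3' UTR. AN, BRK1, KLK, GRL, WRM and DIS1 also had reproducible sites, all in the 3' UTR. No site of these 9 genes was listed in the mock. TRY had 117 events in replicate 1 and 5 in replicate 2 at places that did not overlap. GL1, GL2, GL3, EGL3 and CPC had none, and neither did SIM, at 16.1 ± 0.422 FPKM. A reproducible site was present in 9 of 23 genes (39.1%), against 25.3% of genes of similar input, which did not pass (Fisher's exact test, two-sided, p = 0.148, adjusted p = 0.534 over 14 lists). TTG1, ITB1 and DIS2 are known from published work on ECT2 that used this method, so their presence is not independent evidence.

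**Figure D4:**
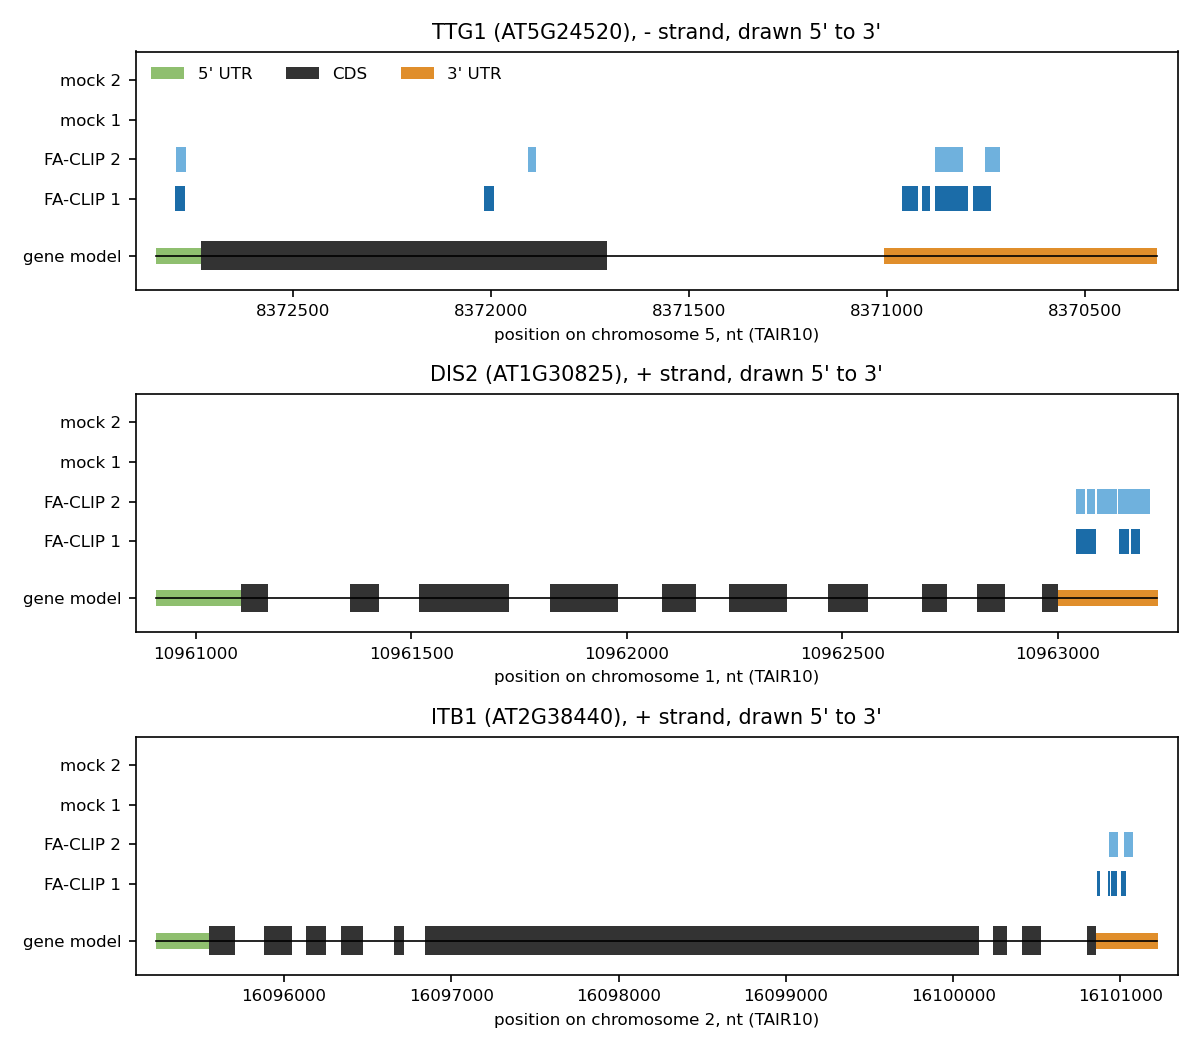
Gene models of TTG1, DIS2 and ITB1, drawn to scale in transcript direction with genomic position on the x axis (nt, TAIR10), and the sites listed in each library as bars above them. FA-CLIP bars lie over the 3' UTR in all 3 genes, and no mock bar is present.

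Where YTH-domain genes other than ECT2 had reproducible sites, these lay in the 3' UTR. ECT1 (AT3G03950) had 39.0 ± 5.66 (SD, n = 2) events in 3 sites, and ECT3, ECT5, ECT6, ECT7, ECT8, ECT11 and CPSF30 had 3 to 11 events in 1 or 2 sites each. ECT2 itself (AT3G13460) had 44.5 ± 3.54 events in 8 sites at 72.2 and 74.9 FPKM, 3 in the 5' UTR and 5 in the CDS. None of its reproducible sites lay in the 3' UTR, where replicate 1 listed 2 sites and replicate 2 listed 1. The FA-CLIP and input plants carried FLAG-tagged ECT2 in the ect2 mutant, so ECT2 RNA may come from the transgene. Its input level and 3' UTR may then differ from those of the native gene. ECT4, ECT9, ECT10 and ECT12 had no reproducible site. None of the 13 genes had a mock site. The 9 of 13 with a site did not pass against 46.2% of genes of similar input (Fisher's exact test, two-sided, p = 0.154, adjusted p = 0.534), and passed only against all genes with input above 0 (adjusted p = 0.0292), which differ in abundance.

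Cytosolic ribosomal protein genes had reproducible sites more often than the pooled genes of nearest input, in 275 of 310 (88.7%) against 64.7% (Fisher's exact test, two-sided, p = 1.7e-20, adjusted p = 2.4e-19), and 84 had a mock site. The pool held 3248 genes, each counted once even where several members shared it, so its input is not weighted as in the list. In the highest of the 10 bins by input, 87.1% of genes had a reproducible site, so a part of the difference may come from input. Chloroplast genome genes had them in 103 of 117 (88.0%) against 75.5% of nuclear genes of similar input (Fisher's exact test, two-sided, adjusted p = 0.00992), but 112 also had a mock site, and without input replicate 1 the difference was 9.23 percentage points and did not pass (adjusted p = 0.116). These are the 2 of 14 lists that passed, adjusted over the 14 lists. Nuclear photosynthesis genes had a site in 37 of 37, and all 37 had a mock site. The housekeeping list had one in 10 of 10, the mRNA decay and poly(A) binding list in 6 of 7, the clock list in 5 of 11, the m6A writer and eraser list in 2 of 8 (HAKAI and VIR), and heat shock genes in 2 of 7. Root markers had one in 0 of 7, structural non-coding RNAs in 73 of 113, mitochondrial genome genes in 12.4% of those with input, and glycine-rich RNA-binding proteins in 2 of 2. None of these passed.

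A score of events per FPKM and per kb, on the log2 scale, compared the amount recovered instead. Cytosolic ribosomal proteins had a median 1.41 above random lists of similar input (permutation p = 2.0e-04, the smallest the lists can give, adjusted p = 0.0022). GRP7 (AT2G21660) and GRP8 (AT4G39260), clock-regulated glycine-rich RNA-binding proteins, differed from them by -5.36 (permutation p = 0.0032, adjusted p = 0.0176). The other 9 lists tested in this way did not pass. This test was added after the data had been seen. The random lists were matched on input and not on transcript length. Most reproducible sites lay in the 3' UTR, so events need not scale with transcript length, and differences in length may enter the score.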

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

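The test of copies dropped at mapping and the test of URUAY and UGUAY among 3' UTR sites were chosen after the result was seen, and GRP7 and GRP8 were noticed in the data before any of their tests.

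Sites were listed at loci which the reference annotation does not hold, and which no comparison examined on their own. They took 0.0558% ± 0.0154 (SD, n = 2) of FA-CLIP events and 0.00891% ± 0.00329 of mock events. AT3G02468 had 144 ± 38.2 FA-CLIP events and 10 and 5 mock events, and AT5G18362 had 135 ± 17 and none in the mock. AT2G33430 had 44.0 ± 12.7, with 35 and 30 in the mock. AT1G48598 and AT5G25752 had 33.5 ± 14.8 and 19.5 ± 6.36, with none in the mock. FA-CLIP replicate 1 listed 37 such loci and replicate 2 listed 21, with 18 in both. No explanation was tested for them.

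GRP7 and GRP8 were abundant in the input, at 274 ± 20.5 and 458 ± 16.5 FPKM, and had 4 ± 1.41 and 3.5 ± 0.707 FA-CLIP events. Their recovery lay on average 6.43 below the median of 320 genes of similar input on the log2 scale. RNase T1 cuts after G, and both transcripts are rich in G. A fit on the G content of whole transcripts predicted -6.81% of the shortfall (SE 4.1), the opposite direction, which argues against overall G content as the cause. Local G-rich stretches were not measured, so digestion at these stays open. GRP7 took 137 times as large a share of protein-coding events in the mock as in FA-CLIP, which argues against reads of near-identical copies being dropped at mapping. That value covers GRP7, since GRP8 had 0 and 5 mock events. Its size rests on few FA-CLIP events. It is also raised by unlike denominators, since protein-coding genes took 5.895% of mock events and 60.3% of FA-CLIP events. No biological explanation was tested, and weak binding by ECT2 stays open.

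FA-CLIP replicate 1 had 33.9% of its sites in coding sequence and replicate 2 had 24.2%, a difference of 9.73 percentage points. Without genes listed in the mock, 104% of it remained (SE 3.1), which argues against background RNA in the genes that the mock lists. Background RNA in other genes was not removed by this test, so it stays open as a cause. Among sites with more than the median number of events 88.5% remained (SE 4.1), and in genes listed in both replicates 93.7% (SE 3.3), which argues against sites near the listing limit and against different genes being listed. Other differences between the libraries, such as digestion, were not tested, and the design gives no biological explanation.

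URUAY was more frequent in FA-CLIP sites than in control windows. Dinucleotide composition left 85.3% of the log2 odds ratio (SE 6.4), which argues against composition as the whole cause. The upper 95% bound of the mock value, 0.323, lay below the lower bounds of 0.346 and 0.448 in the FA-CLIP libraries, but that bound, set beforehand, pooled all regions, and mock sites lay mainly in coding sequence. Among 3' UTR sites the mock had -0.11 and 0.45, with an upper bound of 1.000, against 0.53 and 0.57 in FA-CLIP, and UGUAY, a part of URUAY, passed in mock replicate 2 (1.15, exact test, adjusted p = 0.00916), so RNA that binds the beads without the tag stays open. Against windows with the same number of T, 35.4% remained (SE 9.7), between the bounds set beforehand, so a part of the excess may come from the T content of the called sites, which stays open because only 9925 of 20164 sites had such a window.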

How the results depend on the processing

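Of 58 values of the main results under alternatives, 38 stayed the same and 20 moved. Of the 38, 4 are values of a single FA-CLIP library set against the spread of the 2, which cannot move by construction, which leaves 34 the same of 54. Same means within the spread between replicates or the 95% interval, within 1.5 times for counts, and with direction and side of the threshold kept where there is a test. By that rule the overlap over chance is the same, although its ratio fell from 4.14 to 1.46 when placement kept the region. Most of the main results are counts or shares, which have no direction, so a change of direction could not show in them. The motif result is the number of motifs that passed. It was 6 in the main comparison and 7 against shuffled sites and against windows with the same number of T. That number hides the reversal of UUUUU under both controls. The gene list result is likewise the number of lists that passed. Directions were compared for single motifs and single lists. The alternatives with placement within the region, with nuclear protein-coding genes only for the overlap between replicates, with the authors' location label, without genes listed in the mock, with thinning, with windows of the same number of T, and with the recovery score were chosen after seeing the data, as were the stricter overlap and the upper sites by events for comparisons with the mock and the input at gene level, leaving out mock libraries for the overlap with mock sites, and all alternatives for the named genes.

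Requiring 50% of each site to overlap lowered the sites shared between replicates from 65.2% to 36.7%, reproducible sites that overlap the mock from 13.2% to 7.705%, and genes above the median input with a reproducible site from 59.7% to 47.95%. Sites with more than the median number of events gave 72.0%, 12.3% and 38.6% for these, and 76.8% for the 3' UTR share in place of 63.6%. Thinning lowered the site ratio of FA-CLIP over mock from 23.2 to 18.6. Among genes above the median input, the correlation with abundance was 0.618 in place of 0.666. Against all genes with input above 0, 8 gene lists passed in place of 2. These genes differ from the lists in abundance, and the cause of the other changes was not tested.

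Leaving out 1 library at a time gave 21.1 to 25.9 for the site ratio, 59.7% to 73.9% for FA-CLIP against input, 4.54% to 7.07% for the mock against input, 10% to 10.9% for the overlap with the mock, 0.638 to 0.670 for the correlation with abundance, and 1 to 2 gene lists. With a single FA-CLIP library a gene counts without overlap, which raises the share by construction. The chloroplast list no longer passed without input replicate 1 (9.23 percentage points). FA-CLIP genes without a mock site numbered 7695 to 9941 in place of 7496. They numbered 5847 with 50% overlap and 5044 for sites with more than the median number of events.

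The reversed values were UUUUU, at -0.28 against shuffled sites and -0.25 against windows with the same number of T, the glycine-rich list, at -5.36 by recovery score, and structural non-coding RNAs, 29.4 percentage points above all genes. Of 42 values of single motifs 35 were the same and 5 passed where the main value did not, all GGAU. Of 81 values of single lists 73 were the same. Of the values of single genes 11 moved, all 11 lower, and 39 were the same. Another 50 leave out 1 FA-CLIP library and cannot move by construction, although 11 of them lay more than 1.5 times from the main value, such as RPK2 at 141 in place of 358.5.

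Alternatives chosen in advance but not run were DESeq2, edgeR with library sizes only, recomputed library sizes, another pseudocount, low-value filters, the replicate block, a fit of only the 2 groups, and camera, since no gene-level fit was made. FPKM and events differ in unit, and for site lists the design set overlap of sets, although FA-CLIP and mock events share a unit. No paired analysis was possible because no test across libraries was run that takes a block. That limit comes from the comparisons chosen and not from the design, since the libraries of every group carry replicate numbers. A paired comparison of the shares was not tried. By choice, the shares of each library were set side by side without a test. Sites under 2 events are not listed, which limits what can be said of genes without a site.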

Other observations

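The scan of product words, and the grouping of low words as secretory, were chosen after the data were seen, and the tests of the hypothesis were run on the same libraries.

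The recovery score was compared for 342 words in the product names of 16960 genes, and 40 lay above and 56 below random lists of similar input at adjusted p under 0.05. Words above included nadh (2.2 on the log2 scale, permutation test, adjusted p = 0.00263), ribosomal (1.45) and proteasome (1.38, both adjusted p = 0.00171). Words below included storage (-2.42), lipid-transfer (-2.36), peroxidase (-2.04), lectin (-1.42, these 4 by permutation test at adjusted p = 0.00171) and arabinogalactan (-1.52, adjusted p = 0.00366). Words of membrane proteins lay on both sides. Above were membrane (0.56, permutation test, adjusted p = 0.0102), integral (1.27, adjusted p = 0.0161), syntaxin (1.24, adjusted p = 0.019) and snare (1.19, adjusted p = 0.0216). Below were transporter (-0.47, permutation test, adjusted p = 0.00171), facilitator (-0.73, adjusted p = 0.00263), receptor-like (-0.65, adjusted p = 0.0216), intrinsic (-1.64, adjusted p = 0.0222), permease (-1.02, adjusted p = 0.0237) and exchanger (-1.06, adjusted p = 0.0366), and transmembrane was at -0.03 and did not pass. Words share genes, so these counts are not of independent families. The random lists were not matched on transcript length, by which the score divides.

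Some low words name secreted proteins, and 36% of the 2818 genes in the low families encode an N-terminal hydrophobic segment, against 14.7% of the others. A hypothesis, read off the words, is that mRNAs translated at the endoplasmic reticulum may be less recovered, though words of membrane proteins went both ways. It was tested on the 14142 genes outside those families, of which 2081 encode an N-terminal hydrophobic segment. Their median recovery differed by -0.485 from random lists (permutation p = 2.0e-04, the smallest they can give), and by -0.513 and -0.516 in the 2 libraries. The bound set beforehand was a difference of 0.5, which the pooled value missed, so the hypothesis stays open. Transcript length, 3' UTR length and base composition left 107.9% of the coefficient (SE 8.2), and genes of 10 FPKM or more had 175.8% of it (SE 17), which argues against these and against low abundance as the cause.

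ECT2 itself was 1 of 302 protein-coding genes with 8 or more reproducible sites and an annotated 3' UTR, and 1 of the 4 without a reproducible site in the 3' UTR. This gene was singled out after its values were seen. Its RNA may come from the tagged transgene, whose 3' UTR may differ from the annotated one. In 3' UTRs the pentamer with the highest log2 odds ratio among 976 was ACUCU, at 12.2% of reproducible sites and 4.03% of windows (1.725). It also ranked 1 in both FA-CLIP libraries.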
